A study of Homo sapiens with 10 samples.

How the data were processed

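The values deposited by the authors are raw counts: per the file headers, whole-number UMI counts per gene and cell barcode for the 9 cDNA libraries, and whole-number hashtag counts per hashtag and barcode for the hashtag library, with no normalization. Per the labels the libraries were made with 10x Genomics 3' reagent kits of the v2 chemistry. Per the submitters' processing notes the reads were processed with Cell Ranger 2.0 against the hg19 genome, while the header of the day 14 ventral matrix names software version 3.0.0. How barcodes were called as cells and which tool counted the hashtags are not given in the sources used here. All files list the same 32738 genes. Cells had been frozen and thawed before loading, after Accutase for days 0 to 2 and after an enzyme kit with mechanical dissociation for day 14, per the labels.

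The gene lists, the cell type markers, the rules for naming genes, the tests and most alternatives were fixed before the data were examined. Barcodes with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs passed the cell filter. Scrublet in scanpy 1.11.5 scored doublets, but its own threshold called only 0 to 6 barcodes in each library but the day 14 ventral one, where it called 1161. Doublets were therefore left out by rank of the score, at an expected rate of 0.8% per 1000 barcodes, a rule set after that result was seen. Other settings came from the tools' defaults. The main tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, limma 3.58.1 and Seurat 5.3.0.

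Cells are not replicates, so counts were summed over the kept cells of each library and computed as CPM, a gene's count over each 1000000 summed UMIs. At days 0 to 2 each group was 1 library and nothing was tested. The log2 ratio of CPM + 1 was taken, with exact Poisson intervals for each count and an exact conditional interval for each ratio of CPM. Folds are ratios of CPM without the added 1. Where a gene had 0 counts in 1 library, the least fold that a floor of 3 counts allows is given. For a gene list the median log2 ratio was taken over members with at least 5 CPM in either library and placed among 10000 random lists of the same size matched on mean expression in 20 bins.

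The 25 lists were pluripotency, NODAL and activin targets, BMP targets, WNT targets, SHH pathway targets, SHH repressed receptors, early neuroectoderm, forebrain, midbrain and isthmus, hindbrain, spinal cord, dorsal neural tube, ventral neural tube, neurons, proneural factors, radial glia and progenitors, cell cycle, neural crest, mesendoderm, non-neural ectoderm and placode, mesenchyme, endothelium and blood, choroid plexus and roof plate, hypoxia and glycolysis, and dissociation and stress response. Genes were named by rule. From each list came the 3 measured members with the largest ratio in the direction of the list's median and the 1 with the largest ratio the other way if at least 2-fold. The 8 highest and 8 lowest genes among those at 20 CPM or more joined them, by the ratio of CPM + 5, without mitochondrial, ribosomal protein and clone-named genes. A set of region and pathway genes such as POU5F1, NANOG, PAX6, SP5, PTCH1 and FOXA2 was always reported. A few further list members are given by value only.

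Day 14 libraries were tested with the quasi-likelihood F test of edgeR (glmQLFit and glmQLFTest, TMM scaling, genes kept by filterByExpr, two-sided), with Benjamini-Hochberg adjustment over the genes tested. The 3 dorsal rounds were set against the lone day 14 ventral library, and against the lone day 2 dorsal library, in 2 separate fits. The standard error of a log2 fold change was taken as its size divided by the square root of F. For lists the members past an adjusted p of 0.05 were counted over all genes tested and adjusted over the list alone. A fitted fold change for a gene with 0 counts on 1 side has no upper bound, and the least fold that the 3-count floor allows is printed in its place. For the day 14 dorsal rounds CPM, list sums and class shares are given as mean and SD over 3 rounds.

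Clusters came from scanpy on log-normalised counts (2000 variable genes, 30 principal components, 15 neighbours) with Leiden clustering at resolution 0.5 in the igraph implementation (python-igraph 0.11.9). The dorsal rounds were clustered together and the ventral library by itself. A cluster took a class name from 14 marker sets if at least 3 markers of the class, and more than of any other class, were among the 50 genes with the highest fold against other clusters. Names of 3 ventral clusters, with 669, 1416 and 492 cells, were left off by a rule chosen after the clusters were seen. Of these, 2 had met the roof plate rule although they expressed FOXA2 at 135 and 115 CPM, and the last had met the hindbrain rule although it was led by HOXB9 and HOXC8.

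Of 15980 hashtag barcodes 15877 matched the 16744 barcodes of the day 14 ventral cDNA library. HTODemux in Seurat with a positive quantile of 0.99 called singlets, and the kept singlets of each hashtag were summed. HTODemux called 54.3% of the cells left out by Scrublet score doublets, against 9.27% of kept cells.

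The alternatives tried were every barcode as deposited, a stricter cell filter (2500 UMIs, 1000 genes, 5% mitochondrial), doublets kept, TMM-scaled CPM, the mean of each cell's own CPM, an added 5 CPM in place of 1, and no minimum CPM for list members. For day 14 they were DESeq2, its size factors in edgeR, no filter beyond 1 count, and leaving out each dorsal round. For hashtags a singlet rule of at least 10 counts and 3 times the next hashtag was tried, and for clusters a resolution of 1. After the data were seen, 2 more were added: leaving out barcodes under 0.5% mitochondrial UMIs, and removing the trend of each library with GC content. GC content was taken over the last 500 bases of each gene's longest transcript in GENCODE release 29, which uses another genome build than the files and matched 95.0% of their gene identifiers, so genes are given without coordinates.

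Both methods were run on simulated data made from these counts. In the ratio of 2 libraries the interval covered the true fold for 97.9% of genes changed 2-fold and 94.3% of those changed 4-fold, a list of raised genes came out at percentile 100, and 5 of 100 unchanged lists fell beyond the middle 95%. In the ventral and dorsal day 14 simulation edgeR found 70.0% of genes changed 2-fold and 100% of those changed 4-, 8- or 16-fold, and called 34 of 17589 unchanged genes. In the day 14 and day 2 simulation it found 64.0% of 2-fold changes and called 25 of 17351 unchanged genes. In both edgeR simulations every library, the lone one included, was drawn from the mean of the dorsal rounds with the fitted spread. The lone library thus had no shift of its own from batch, chemistry or processing. The counts of unchanged genes called do not cover calls that such a shift would cause in the real data.

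Left out were mapping of reads, since the analysis began from the counts given, any correction for free RNA, and trajectories. Y-linked genes were left out of the texts, and some other genes are not reported here.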

Results

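Single-cell 3' RNA sequencing counted transcripts in human neural tube tissue grown from H9 cells, an established embryonic stem cell line. In this model, called MiSTR tissue, a microfluidic device passes a gradient of CHIR99021, an activator of WNT signalling, over the cells so that positions along the tissue may take on head-to-tail identities. From day 1 to day 9 the medium held 10 µM SB431542, which blocks NODAL and activin receptors, 100 ng/ml Noggin, which blocks BMP, and CHIR99021 from 0 to 2 µM. Ventralised tissue also received 200 ng/ml of the SHH-C24II protein and 0.5 µM purmorphamine, both activators of SHH signalling, and tissue without them is called dorsal here. The 10 samples were 9 cDNA libraries and 1 library of hashtag counts. Day 0, day 1 dorsal, day 1 ventral, day 2 dorsal and day 2 ventral had 1 library each, made from 3 tissues pooled before loading. Day 14 dorsal tissue had 3 libraries, called rounds, and day 14 ventral tissue had 1 library whose cells carried 5 hashtags for 5 regions of the tissue.

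After filtering, 57171 of 63604 barcodes were kept as cells. The kept molecules (UMIs) per library were 65664592 at day 0 (7499 cells), 20597754 at day 1 dorsal (952 cells) and 94764590 at day 1 ventral (7900 cells). Day 2 dorsal had 20413556 UMIs in 4035 cells and day 2 ventral 87320797 in 5744 cells. The day 14 dorsal rounds had 63764833, 49637378 and 69498286 UMIs in 6658, 5005 and 5581 cells, and the day 14 ventral library 197457837 UMIs in 13797 cells. The median per kept cell ran from 4603 UMIs at day 2 dorsal to 14762 at day 2 ventral. In the day 1 dorsal library 58.7% of kept cells had under 0.5% mitochondrial UMIs, against 2.02% to 7.0% in the other libraries. Those day 1 dorsal cells had a median of 8193 UMIs, against 38524 in the other 393 kept cells of that library, which weigh more per cell in its summed counts. Expression is given as CPM, a gene's count over each 1000000 UMIs of those summed over a library's kept cells. With 1 library per group at days 0 to 2 no spread between samples could be had there, so all intervals at those days are 95% intervals for counting error only.

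The comparison of day 1 dorsal tissue with day 0 asks what the first day of dual inhibition and WNT activation did to the stem cells. NODAL and BMP target genes were far lower than at day 0, WNT target genes were higher, and the core stem cell factors were split. NANOG was nearly gone while POU5F1 was only moderately lower and SOX2 was higher. Genes of the neural plate as a group were not yet different from day 0. NANOG (ENSG00000111704), which holds cells in the pluripotent state, was at 3.20 CPM against 66.9 at day 0, 20.9-fold lower (16.4 to 27.1). UTF1, a chromatin factor of stem cells, was 20.2-fold lower and L1TD1, an RNA-binding protein of stem cells, 2.13-fold lower. POU5F1 (ENSG00000204531) stood at 693 CPM against 1188, 1.71-fold lower (1.68 to 1.74), and SOX2, shared by stem cells and neural progenitors, was 2.36-fold higher. Over 14 measured pluripotency genes the median log2 ratio was -0.60, lower than in all but 0.06% of 10000 random lists matched on expression. Among NODAL and activin targets LEFTY1, a feedback inhibitor of NODAL, went from 33.5 CPM to 1 count (0.0485 CPM), SMAD7 was 28.7-fold lower and SKIL 10.6-fold lower. FOXH1, the partner of SMAD proteins on DNA, was instead 2.40-fold higher, and the list median was -3.02, with 6 of 7 genes at least 2-fold lower. Of the BMP targets ID1 was 5.94-fold lower, ID3 5.28-fold lower and BAMBI 16.5-fold lower, with a list median of -2.39 and 4 of 5 genes at least 2-fold lower. DUSP6, a target of FGF and ERK signalling, was 54.6-fold lower, at 4.71 CPM against 257.

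WNT targets moved the other way in that library, with a median of 1.92 over 6 measured genes of the 15 listed, 1.19 with 5 CPM added and 0.50 with no minimum CPM. SP5, a direct target of beta-catenin, was at 59.2 CPM against 0.259 (229-fold higher, 142 to 394), LEF1 was 14.4-fold higher, NKD1 7.35-fold higher and AXIN2 2.97-fold higher (2.57 to 3.43). PTCH1, the SHH receptor and target, was 4.14-fold higher without added SHH, from 1.69 to 6.99 CPM. Early neuroectoderm genes had a median of 0.04, at percentile 74.7 of random lists, because its members were split. FEZF1 was 8.69-fold higher, OTX2 2.64-fold higher and SOX11 1.76-fold higher, while the eye field factor SIX6 had 0 counts and was at least 74.6-fold lower. SOX21 (58.8-fold), OLIG3 (at least 230-fold from 0 counts) and the hindbrain gene GBX2 (5.06-fold) were higher too. The dorsal neural tube list had a median of 1.30 and the forebrain list -1.39, the latter with 3 of 5 genes at least 2-fold lower, among them EMX1 and HESX1, and 2 at least 2-fold higher. The neuronal gene STMN2 was 9.59-fold higher, FST, a secreted activin blocker, 12.4-fold higher, and DDIT4, an inhibitor of mTOR, 22.5-fold higher. Among genes over 20 CPM the highest ratio of CPM + 5 was for CUZD1, at 207 CPM against 0.472.

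The comparison of day 1 ventral tissue with day 0 asks the same question with SHH activation added. The same loss of NODAL and BMP targets and gain of WNT targets was seen. PTCH1 and FOXA2, already above day 0 in day 1 dorsal tissue, were further above it here. NANOG was at 3.09 CPM, 21.6-fold lower (19.2 to 24.4), UTF1 15.7-fold lower and POU5F1 1.81-fold lower (1.79 to 1.83), while SOX2 was 2.44-fold higher. The pluripotency median was -0.80. Below day 0 were also LEFTY1 (635-fold), SMAD7 (42.5-fold), SKIL (15.8-fold), BAMBI (12.2-fold) and ID3 (4.08-fold), with list medians of -2.88 for NODAL and activin targets and -1.79 for BMP targets. WNT targets had a median of 1.89 (0.98 with no minimum CPM), with SP5 271-fold higher (169 to 465), LEF1 15.6-fold, NKD1 7.97-fold and AXIN2 2.65-fold higher. PTCH1 (ENSG00000185920) was at 15.1 CPM, 8.94-fold above day 0 (7.37 to 10.9). FOXA2 (ENSG00000125798), the factor that sets up the floor plate and is also an endoderm gene, was at 6.01 CPM against 0.32, 18.8-fold higher (12.2 to 30.6). It was the only measured gene of both the ventral neural tube and the mesendoderm lists. Early neuroectoderm genes had a median of -0.00, with FEZF1 5.64-fold higher and HESX1 4.34-fold lower. GBX2, IRX2 and STMN2 were 4.96-, 17.5- and 11.7-fold higher. IGFBP5, which binds insulin-like growth factors, was 62.9-fold higher.

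The comparison of day 2 dorsal tissue with day 0 asks how far the cells had left the stem cell state after another day. Most pluripotency genes, including POU5F1, were now below day 0, while the medians of neural plate and neural progenitor genes were above it. POU5F1 was at 168 CPM, 7.07-fold lower (6.83 to 7.32), NANOG 56.9-fold lower, UTF1 126-fold lower and L1TD1 11.9-fold lower. TDGF1, the NODAL co-receptor, was at 1.47 CPM against 404, 275-fold lower (192 to 407), and LEFTY1 and the pluripotency and neural crest gene FOXD3 had 0 counts, at least 228- and 169-fold lower. The list medians were -1.85 for pluripotency, with 9 of 14 genes at least 2-fold lower and 2 at least 2-fold higher, -3.58 for NODAL and activin targets and -2.99 for BMP targets. Of 6 BMP targets 4 were at least 2-fold lower and 2 at least 2-fold higher, among them ID2 at 3.14-fold. The epithelial genes EPCAM, KRT18 and CDH1 were 11.6-, 11- and 5.64-fold lower and CDH2, the neural cadherin, 2.59-fold higher. The non-neural ectoderm list had a median of -2.27.

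On the neural side at day 2 dorsal the early neuroectoderm median was 0.77 and that of radial glia and progenitors 0.82, both at percentile 100 of random lists. Of 10 early neuroectoderm genes 4 were at least 2-fold higher, 2 at least 2-fold lower and 4 within 2-fold, and with no minimum CPM the median was 0.16. Of 14 progenitor genes 5 were at least 2-fold higher and 9 within 2-fold. PAX6 (ENSG00000007372), the neuroectoderm master regulator, was at 2.45 CPM against 0.274, 8.94-fold higher (5.12 to 16.3), so it was still low in absolute terms. LMO1 was 50.4-fold higher, LIX1 15.2-fold, SOX11 5.63-fold, SIX3 3.28-fold and SOX21 42.6-fold higher. The diencephalic factor LHX5 was 35.7-fold and the midbrain factor PAX2 37.3-fold higher. MEIS2, a HOX cofactor of the caudal brain, was 253-fold higher. HOXB2 had 0 counts at day 0 and 0.588 CPM here, at least 12.9-fold more. WNT targets had a median of 2.46 (0.79 with no minimum CPM), with SP5 170-fold, TNFRSF19 84.8-fold, NKD1 19.0-fold and AXIN2 2.58-fold higher, and PTCH1 was 7.19-fold higher (5.72 to 9.07). DLK1, an imprinted NOTCH ligand homologue, was at 556 CPM against 5.18 (107-fold), DDIT4 was 38.8-fold and the hypoxia gene BNIP3 6.56-fold higher, and the hypoxia list had a median of 0.72. NTS and the metallothionein MT2A were 984- and 19.9-fold lower.

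The comparison of day 2 ventral tissue with day 0 asks the same with SHH activation. As in dorsal tissue, the medians of stem cell genes were lower and those of progenitor genes higher, and PTCH1 was further from day 0 than at day 1. POU5F1 was at 305 CPM, 3.90-fold lower (3.84 to 3.95), NANOG 77.9-fold lower, TDGF1 154-fold lower and L1TD1 7.15-fold lower, with a pluripotency median of -1.85. NODAL and activin targets had a median of -3.60 and BMP targets -3.47, with ID1 12.8-fold and BAMBI 58.7-fold lower, and 4 of 5 BMP targets at least 2-fold lower and 1 at least 2-fold higher. PTCH1 was at 31.1 CPM, 18.4-fold higher (15.2 to 22.4), GLI1, the transcription factor turned on by SHH, 2.79-fold higher and FOXA2 at 7.54 CPM, 23.6-fold higher (15.3 to 38.3). WNT targets had a median of 2.04 (0.63 with no minimum CPM), with SP5 226-fold, NKD1 22.7-fold and AXIN2 2.02-fold higher. The early neuroectoderm median was 0.88 (0.0665 with no minimum CPM), with 5 of 10 genes at least 2-fold higher and 1 at least 2-fold lower, LMO1 49.2-fold, LIX1 14.7-fold and FEZF1 6.29-fold higher, and that of radial glia and progenitors 0.79, with VIM 3.49-fold and TTYH1 3.80-fold higher. PAX6 was 5.56-fold, OTX2 2.59-fold, LHX5 51.7-fold and PAX2 48.7-fold higher. FGF17, an isthmus signal, was 84.0-fold higher, at 5.12 CPM. EPCAM, CDH1 and KRT18 were 5.84-, 6.54- and 9.13-fold lower, and DLK1 was 145-fold higher. TMM scaling would raise the log2 ratios to day 0 by 0.17 at day 1 ventral, 0.17 at day 2 dorsal and 0.25 at day 2 ventral.

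**Figure D1:**
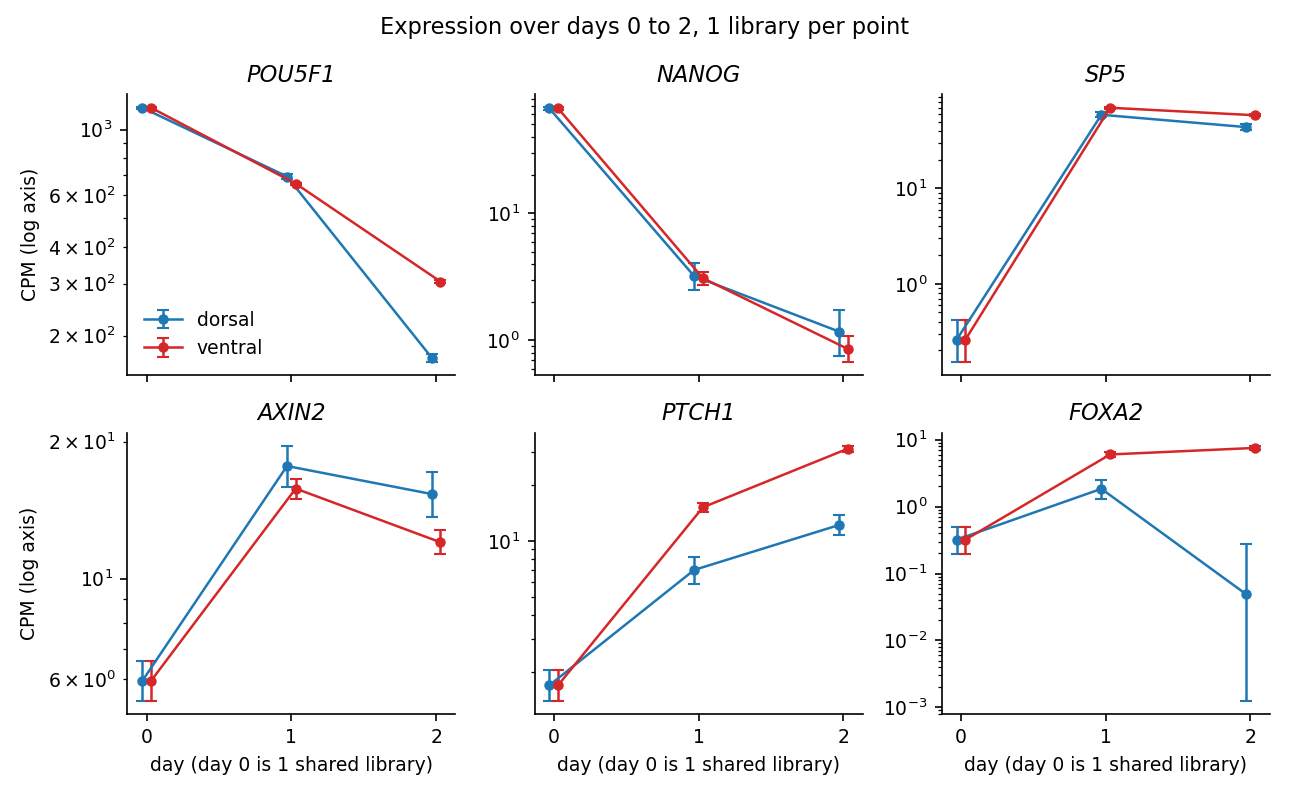
CPM (log axis) of 6 genes by day in dorsal and ventral tissue. Each point is 1 library, the bars are 95% Poisson intervals, and day 0 is the same library in both lines. At day 2 PTCH1 was at 12.1 CPM in dorsal and 31.1 in ventral tissue, and FOXA2 at 0.049 and 7.54.

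**Figure D2:**
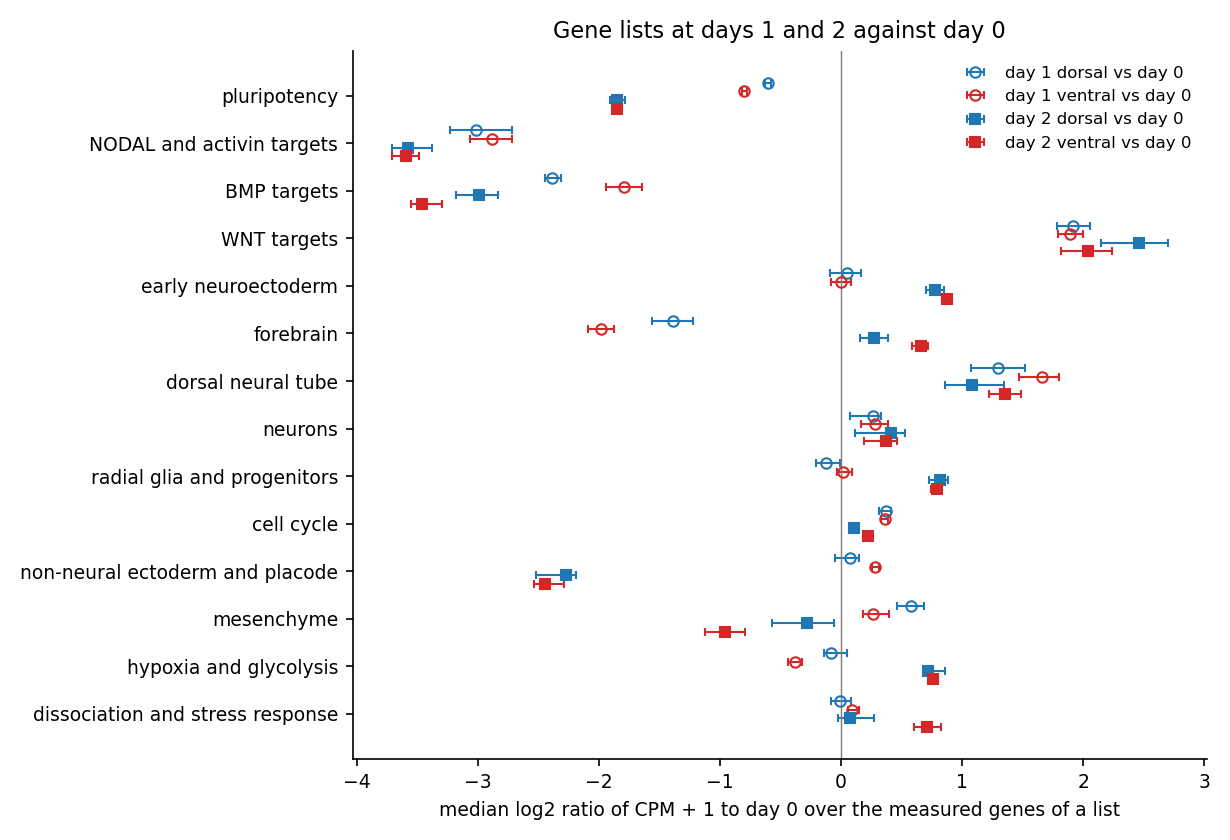
Median log2 ratio to day 0 of CPM + 1 over the measured genes of each list with at least 4 measured genes in all 4 comparisons, for the 4 libraries of days 1 and 2. Bars are 95% intervals from 400 Poisson resamples of the counts. Pluripotency, NODAL and BMP medians lie left of 0 and WNT medians between 1.89 and 2.46.

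Ventral was compared with dorsal tissue at day 1 to ask how soon added SHH activators separated them. Among the listed genes PTCH1 and FOXA2 of the SHH response were clearly higher in ventral tissue, while most stem cell, WNT and neural plate genes were close. PTCH1 was at 15.1 CPM in ventral and 6.99 in dorsal tissue, 2.16-fold higher (1.82 to 2.58), and FOXA2 at 6.01 and 1.84 CPM, 3.26-fold higher (2.35 to 4.66). The SHH pathway list had a median of 1.01, which rested on PTCH1 alone, since GLI1 stayed under 5 CPM in both libraries at 4.64 and 4.32 (1.07-fold, 0.854 to 1.37). With barcodes under 0.5% mitochondrial UMIs left out, GLI1 at 5.31 CPM entered the list and the median was 0.29, although PTCH1 was still higher at 15.2 against 8.79 CPM. NANOG was at 3.09 and 3.20 CPM, POU5F1 at 656 and 693 and AXIN2 at 15.8 and 17.7. SP5 was 1.18-fold higher. The medians were -0.08 for pluripotency, 0.11 for WNT targets and -0.25 for early neuroectoderm, with FEZF1 1.54-fold and HESX1 1.58-fold lower in ventral tissue. BMP targets had a median of 0.37, with ID1 1.88-fold (1.68 to 2.12) and ID3 1.29-fold higher. HES4, a NOTCH target, was 1.98-fold and SOCS1 2.08-fold higher. Lower in ventral tissue were the glycolysis regulators PFKFB3 (2.00-fold) and PDK1 (1.85-fold), MIF (2.75-fold) and the replication gene MCM5 (1.65-fold). The hypoxia list had a median of -0.37, below all but 0.03% of random lists. NKX2-1, EN1 and HOXB2 had no more than 2 counts in either library, so a difference was not detectable at this depth. The dorsal library held 952 cells, most with few mitochondrial UMIs and, at the median, far fewer UMIs than its other cells. TMM scaling would raise these log2 ratios by 0.10.

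At day 2 the same comparison asks whether the separation had widened. It had for FOXA2, but mostly because the dorsal value fell to 1 count, while the ventral value was little above that of day 1. The intervals of the PTCH1 ratio at days 1 and 2 overlap. Some dorsal identity genes were now lower in ventral tissue. Of 6 measured genes of the dorsal neural tube list 1 was at least 2-fold lower and 5 within 2-fold, and all 11 measured pluripotency genes were within 2-fold. FOXA2 was at 7.54 CPM in ventral tissue against 1 count (0.049 CPM) in dorsal tissue, 154-fold higher (27.5 to 6085). PTCH1 was at 31.1 against 12.1 CPM (2.56-fold, 2.25 to 2.93) and GLI1 at 5.27 against 3.28 (1.61-fold, 1.24 to 2.11), for an SHH list median of 0.92. MSX1, a roof plate gene and BMP target, was at 1.39 against 6.32 CPM, 4.56-fold lower (3.53 to 5.89), ZIC2 2.19-fold, OLIG3 1.57-fold and GLI3, the repressor form of which sets dorsal fate, 1.45-fold lower. SOX11 was 2.61-fold, HES1 1.96-fold, CDH2 1.68-fold, SOX9 1.66-fold and the FGF inhibitor SPRY1 2.95-fold lower in ventral tissue. The dorsal neural tube list had a median of -0.34, at percentile 3.18 of random lists, and WNT targets -0.40, with TCF7 1.73-fold and LEF1 1.40-fold lower but SP5 1.33-fold higher. SOX3, a neural progenitor factor, was 4.45-fold higher (3.04 to 6.76). The forebrain list had a median of 0.52, with FEZF1 1.51-fold, LHX5 1.45-fold and HESX1 1.31-fold higher, and OTX2 was 1.69-fold higher. POU5F1 was 1.82-fold (1.75 to 1.88), L1TD1 1.67-fold and EPCAM 1.99-fold higher in ventral tissue, and the pluripotency median was 0.25, at percentile 92.5. Among genes at 20 CPM or more the largest ratios of CPM + 5 were the lower values of GABARAP (18-fold), EEF1G (15.4-fold), GPM6A (13.0-fold), SLITRK4 (9.94-fold) and CXCL14 (9.28-fold). The dorsal library had 4603 UMIs per cell at the median against 14762.

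Day 14 ventral tissue was compared with day 14 dorsal tissue to ask which cell identities went with the SHH activators. Ventral tissue expressed floor plate and ventral forebrain regulators that dorsal tissue nearly lacked. Dorsal tissue expressed more PAX6 and more of some genes of the dorsal neural tube list, such as EMX2, though that list went both ways. SHH itself rose along with its targets PTCH1 and HHIP, and 3 of 5 co-receptors and GLI factors that SHH represses fell. Of 20 cell cycle genes 15 were lower in ventral tissue and 1 was higher, and most neuronal genes were not clearly different. Of 18670 genes tested with edgeR, 5028 rose and 4281 fell at a Benjamini-Hochberg adjusted p under 0.05, of which 3362 and 1201 by at least 2-fold. DESeq2 with Benjamini-Hochberg adjustment called 4394 higher and 4647 lower, so which direction had more genes depends on the method.

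In the edgeR test all 13 measured genes of the ventral neural tube list rose, with a median log2 fold change of 5.15. NKX2-1 (ENSG00000136352), which specifies the hypothalamus and ventral telencephalon, was at 146 CPM in ventral and 0.00480 ± 0.00831 CPM (SD, n = 3) in dorsal tissue, where it had 1 count over all 3 rounds, a log2 fold change of 14.13 that rests on that count, with an edgeR adjusted p of 8.42e-05. SHH (ENSG00000164690) was at 293 against 1.34 ± 0.794 CPM (log2 fold change 7.50, SE 0.52, edgeR adjusted p 0.000713). FOXA2 was at 105 against 0.501 ± 0.329 CPM (7.46, SE 0.49, edgeR adjusted p 0.000630) and FOXA1 at 106 against 0.305 ± 0.197 CPM. The floor plate genes NTN1 (112 CPM), which guides axons, and CORIN (50.9 CPM) rose. So did the domain markers NKX2-2 (41.6 CPM), NKX6-1 (34.0 CPM), NKX6-2 (59.9 CPM) and OLIG2 (8.22 CPM). Ventral forebrain and eye field genes rose, with SIX6 at 67.3 against 0.149 CPM, SIX3 at 135 against 7.85 ± 2.87 CPM, RAX at 35.9 against 1.94 CPM and VAX1 at 8.21 CPM. The forebrain list had 9 genes up and 4 down of 14, with a median of 1.97.

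Of SHH pathway genes PTCH1 rose from 25.6 ± 8.38 to 95.1 CPM (log2 fold change 1.61, SE 0.33, edgeR adjusted p 0.0133), HHIP, a decoy receptor, rose from 1.89 to 23.1 CPM, and GLI1 at 1.16 against 0.681 CPM did not pass. Of 5 genes repressed by SHH 3 fell, with GLI2 at 3.31 against 16.2, GLI3 at 9.96 against 41.4 ± 3.29 and BOC at 14.2 against 43.6 CPM, while GAS1 and CDON did not pass. GLI2 was also at least 3-fold lower in the ventral library than in any other, early ones included, a pattern whose cause was not tested. PAX6 and LHX5, which are not in the dorsal neural tube list, fell as well, as did some genes of that list. PAX6 was at 18.3 against 282 ± 29.7 CPM (log2 fold change -4.24, SE 0.15, edgeR adjusted p 0.000226) and EMX2, a cortical factor, at 2.91 against 67.7 ± 3.62 CPM. LHX5 was at 7.06 against 90.3 CPM, PAX3, of the dorsal tube and crest, at 0.679 against 22.6 ± 20.3 CPM (edgeR adjusted p 0.0238), and the roof plate signal RSPO1 at 0.314 against 8.73 CPM. TRH, the thyrotropin-releasing hormone, fell from 135 to 2.08 CPM. The 13 measured genes of the dorsal neural tube list went both ways, with a median of -1.04, below all random lists. Without round 1, which had the most PAX3, this median was -0.21, so its size depends on the round. In plain CPM, without the TMM scaling of the fit, it ran from -1.48 to 0.21 against single rounds. In that measure its sign depended on the round.

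NOTCH effectors of progenitors rose, with HES1 at 285 against 6.53 ± 2.40 CPM, HES5 at 262 against 12.6 and HES4 at 198 against 14.5. VIM and NES rose as well, to 4873 and 585 CPM. Of 17 radial glia and progenitor genes 10 rose and 4 fell, or 11 and 4 when adjusted over the list alone, while SOX2 just missed (edgeR adjusted p 0.0532). Of 20 cell cycle genes 15 fell and 1 rose, with 15 and 2 when adjusted over the list alone. The list median was -0.66, against -0.354 for random lists of like expression, and in plain CPM -0.45 to -0.32 against single rounds. PCNA was at 118 against 240 ± 1.62 CPM, AURKB at 47.1 against 100 and MCM5 at 34.5 against 64.6. TOP2A was the gene that rose, and MKI67 at 87.9 against 65.8 CPM did not pass. The proneural genes INSM1 and DLL3 rose to 25.9 and 46.8 CPM and NEUROG1 fell to 1.55 CPM. Of 18 neuronal genes 2 rose and 1 fell, with STMN2 at 224 against 301 ± 115 CPM (edgeR adjusted p 0.221). TTR, the transthyretin of choroid plexus, rose to 220 from 1.68 ± 2.35 CPM, and the other 5 measured genes of the choroid plexus and roof plate list did not pass. IGFBP2 at 1856 against 52.0 CPM, JUND at 521 against 12.2 and TFF3 at 208 against 3.59 rose as well. IGFBP2, JUND and NES were at least 3-fold above every other library, early ones included, and the cause of that pattern stays open. OTX2, EN1, HOXB2, FGF17 and SP5 did not pass, and EN1, HOXB2, FGF17 and SP5 varied among the dorsal rounds by more than their mean.

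Each p of the day 14 tests measured only the spread among 3 dorsal rounds, with 2 residual degrees of freedom and the lone library taken to vary like them, and the labels do not say that rounds were separate tissues. The ventral library also shared only 1 to 3 barcodes with each other cDNA library, where the others shared 3 to 97, its matrix header names software version 3.0.0, and TMM scaling lowered its log2 fold changes by 0.29 from plain CPM. So few shared barcodes point to another barcode set than in the other libraries. Any difference in chemistry or read processing coincides with tissue type here. No call between ventral and dorsal tissue at day 14 can therefore be assigned to the SHH activators alone.

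**Figure D3:**
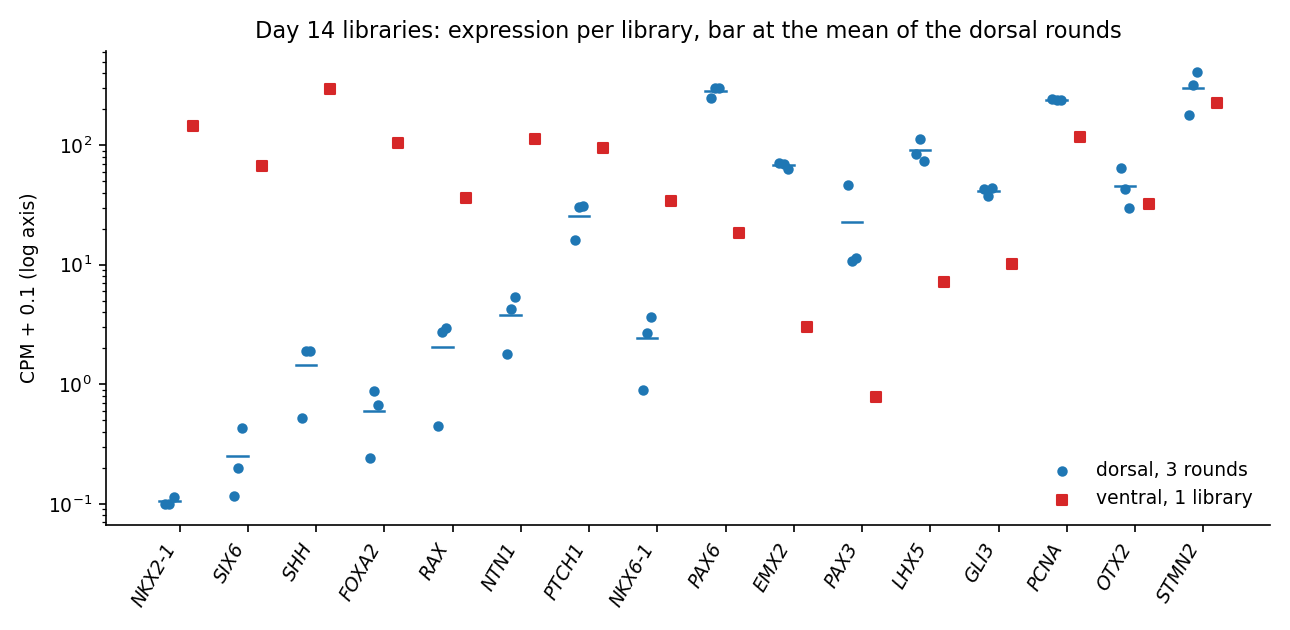
CPM + 0.1 (log axis) of 16 genes in each day 14 library. Circles are the 3 dorsal rounds with a line at their mean, and squares the 1 ventral library. NKX2-1 was at 146 CPM in the ventral library and PAX6 at 18.3 CPM against a dorsal mean of 282.

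Day 14 dorsal tissue was compared with day 2 dorsal tissue to ask how the tissue had matured. Most stem cell genes and some early WNT targets fell, most neuronal genes rose, and forebrain and hindbrain genes went both ways. Of 18138 genes tested with edgeR, 4320 rose and 4100 fell at a Benjamini-Hochberg adjusted p under 0.05. POU5F1 fell from 168 to 0.345 ± 0.0275 CPM (SD, n = 3; log2 fold change -8.95, SE 0.09, edgeR adjusted p 4.18e-05). ZFP42, a stem cell zinc finger gene, fell from 36.8 to 0.501 CPM, L1TD1 from 63.9 to 4.82 and the stem cell microRNA host transcript MIR302B from 943 to 0.352. NANOG was already low at day 2 and did not pass. Of 11 pluripotency genes 8 fell and 1 rose (9 and 1 when adjusted over the list alone), with a median of -1.73. SP5 fell from 43.9 to 0.699 CPM, NKD1 from 39.9 to 4.86 and AXIN2 from 15.3 to 7.26 (edgeR adjusted p 0.0426, above 0.05 without round 2 or round 3), and 4 of 7 WNT targets fell. HESX1, of the early anterior plate, fell from 41.8 to 2.09 CPM, OLIG3 from 19.8 to 0.535, APOE from 1226 to 21.2 and PAX2 from 13.1 to 2.87.

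PAX6 rose from 2.45 to 282 ± 29.7 CPM (log2 fold change 6.82, SE 0.20, edgeR adjusted p 0.000563). NR2F1, a nuclear receptor of the forebrain and hindbrain, rose from 1 count (0.049 CPM) to 138 ± 17.1 CPM, and NR2E1 from 0 counts to 12.3 CPM, at least 80.9-fold. Of 9 forebrain genes 5 rose and 1 fell, and of 7 hindbrain genes 3 rose, among them HOXA2 to 18.7 CPM, and 2 fell, with a hindbrain list median from -0.42 to 2.73 over single rounds. Of 17 neuronal genes 15 rose and none fell, or 16 when adjusted over the list alone, with a median of 2.26. ELAVL4, a neuronal RNA-binding protein, rose from 0.245 to 65.9 ± 25.5 CPM (edgeR adjusted p 0.00257), STMN4 from 2.84 to 63.0, STMN2 from 61.1 to 301 ± 115 and SNAP25, a synaptic protein, from 0 counts to 9.53 CPM. The proneural genes DLL1 (0.539 to 91.7 CPM) and NEUROG1 (from 0 counts to 12.7) rose, and none of 7 in that list fell. Among progenitor genes FABP7 rose from 16.3 to 373 ± 44.1 CPM and HES5 to 12.6 CPM, and HES1 fell from 27.9 to 6.53, with 9 of 17 up, 2 down and a median of 1.28. ZBTB16, a factor of neural rosettes, rose to 107 CPM and NTRK2, a neurotrophin receptor, to 88.8 ± 25.8 CPM. GLI3, BOC and GAS1 rose, to 41.4, 43.6 and 13.8 CPM, and PTCH1 at 25.6 against 12.1 CPM did not pass. The neural crest list had 4 of 6 genes up, with PAX3 at 22.6 ± 20.3 CPM. Of 16 stress response genes 11 rose (12 when adjusted over the list alone), among them JUNB from 3.92 to 26.8 CPM, and day 14 cells had been dissociated with an enzyme kit, where day 2 cells were treated with Accutase.

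The 3 day 14 dorsal rounds were compared with each other to ask how reproducible the tissue was. Most genes were alike, and those that differed most included FGF17, HOXB2, HOXB1, RSPO2, ID3, DLK1 and PTN. Among 5017 genes at 20 CPM or more the median coefficient of variation was 5.20% (3.27% without round 1), and 37 genes (0.737%) differed at least 2-fold. Round 1 expressed isthmus and roof plate genes, with FGF17 at 121, 7.27 and 0.130 CPM in rounds 1 to 3, RSPO2 at 59.7, 9.85 and 2.45, PAX3 at 46.0, 10.6 and 11.2 and ID3 at 330, 82.2 and 65.9. Round 3 expressed hindbrain genes, with HOXB2 at 0.188, 22.3 and 69.1 CPM and HOXB1 at 0.125, 12 and 62.3. DLK1 was at 328, 1238 and 1483 CPM, and PTN at 621, 198 and 159. The summed CPM of the midbrain and isthmus list was 224, 65.1 and 28.5 and that of the hindbrain list 28.5, 82.3 and 195. The median ratio of highest to lowest round was 2.84 and 2.57 in these lists, but also 2.43 for neural crest genes and 2.41 for BMP targets, and 1.08 for cell cycle genes. The cell cycle list varied little, at 2903 ± 49.1 CPM, and the neuronal list was at 1302 ± 244 and the forebrain list at 302 ± 66.6. With 3 samples of 1 group no test between rounds was possible.

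The dorsal rounds were clustered together to ask which cell types they held. Forebrain progenitor-like cells, led by TRH, FEZF1 and LHX5 with EMX2 and NR2E1, made up 23.7% ± 7.48 (SD, n = 3) of kept cells. Their share of round 3 was 22.2%, but 35.5% when round 2 was left out and 35.4% with the strict cell filter. Hindbrain progenitor-like cells, led by HOXB1, HOXB2 and HOXA2, made up 9.78% ± 10.8, from 0.946% in round 1 to 21.8% in round 3. This share depends on the resolution, at 0.391% of round 1 and 3.64% of round 2 at Leiden resolution 1, and on which rounds are clustered together, since without round 3 it was 8.02% of round 1 and 24.8% of round 2, against 6.59% of round 2 with all rounds. Roof plate or choroid plexus-like cells, with RSPO2, LMX1A and TTR, went the other way, from 13.9% to 0.0179%. Neuron-like cells, with STMN2, NEFM, GAP43 and ELAVL3, made up 5.53% ± 1.97, but 73 of them lay in a cluster led by GATA3, GAD2 and SLC32A1, with none of these markers among its 10 leading genes. Neural crest-like cells made up 1.12% ± 0.659, in a cluster also led by the mesenchymal genes LUM and DCN, and floor plate-like cells 0.420% ± 0.329, a class that was not found at Leiden resolution 1 or without round 1. The other 54.5% ± 7.78 lay in clusters that took no name by the marker rule. One of these, led by FGF17 and PAX8, made up 19.2% of round 1 and 0.0717% of round 3.

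**Figure D4:**
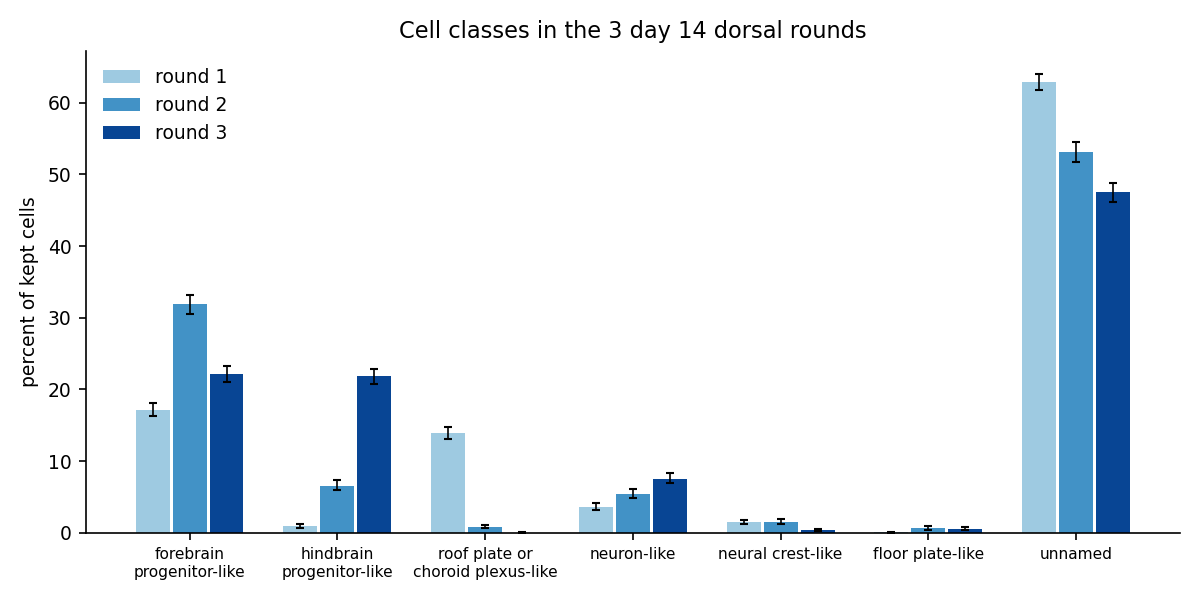
Percent of kept cells in each cell class in the 3 day 14 dorsal rounds, with exact 95% binomial intervals as bars. Hindbrain progenitor-like cells ranged from 0.946% to 21.8% and roof plate or choroid plexus-like cells from 13.9% to 0.0179%.

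In the day 14 ventral library the neuron-like class made up 966 of 13797 kept cells, 7.0% (6.58 to 7.44, exact Clopper-Pearson). Of these, 672 lay in a cluster whose 10 leading genes held more markers of neuronal precursors (NHLH1, NEUROD1, INSM1) than of neurons (STMN2, ELAVL3), so the class is not of neurons alone. Its other named classes were forebrain progenitor-like, in 4 clusters, hindbrain progenitor-like with 316 cells and mesenchyme-like with 26. SIX6 and RAX were leading genes in 2 of the 4 clusters, and the others were led by NOS2 and FEZF2 and by PAX6 and FEZF1. With the strict cell filter no hindbrain progenitor-like or mesenchyme-like class was found. Neuron-like shares were not compared between dorsal and ventral tissue, since they were clustered apart and the class took in clusters led by other genes in each.

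The hashtags in day 14 ventral tissue ask whether regions of the tissue differed along the gradient. The hashtag names do not say which region each marked, so the pools are unordered. Of 13479 kept cells with a hashtag 11501 carried 1 only (85.3%, 84.7 to 85.9, exact Clopper-Pearson), 1249 were called doublets and 729 had none. The 5 pools held 1543 to 3062 cells and 19856134 to 48344636 UMIs. Ventral forebrain genes were highest in pools HTO1 and HTO2, and the floor plate genes SHH, NTN1 and FOXA2 were highest in HTO3 to HTO5 but not confined to them. NKX2-1 was at 471, 464, 41.2, 8.13 and 6.31 CPM in pools HTO1 to HTO5, SIX3 at 449, 424, 43.0, 3.68 and 4.40 and SIX6 at 334, 145, 6.62, 2.30 and 2.12. FGF8, a signal of the anterior neural ridge, was highest in HTO1 at 99.5 CPM, and FEZF2 and RAX in HTO2 at 117 and 126 CPM. HTO3 had the most EN1 (39.2 CPM), LMX1A (32.2 CPM) and DMRTA2 (76.3 CPM), which in ventral cells mark the midbrain floor. SHH was at 105, 173, 255, 410 and 353 CPM, and NTN1 at 13.8, 18, 99.0, 173 and 160 CPM. FOXA2 was at 20.1, 54.3, 131, 131 and 129 CPM, and with every barcode kept its top pool was HTO3 and not HTO4. HOXB2 was at 0.856, 1.67, 1.63, 17.7 and 70.2 CPM. HOXB9, a spinal cord gene, was at 26.1 CPM in HTO4 and 17.5 in HTO5. OTX2, which ends at the hindbrain border in the embryo, was at 33.8, 91.1, 62.3, 2.44 and 1.15 CPM. STMN2 was highest in HTO1 at 669 CPM and lowest in HTO4 at 53.3. Each pool is 1 sample, so no test between pools was possible.

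**Figure D5:**
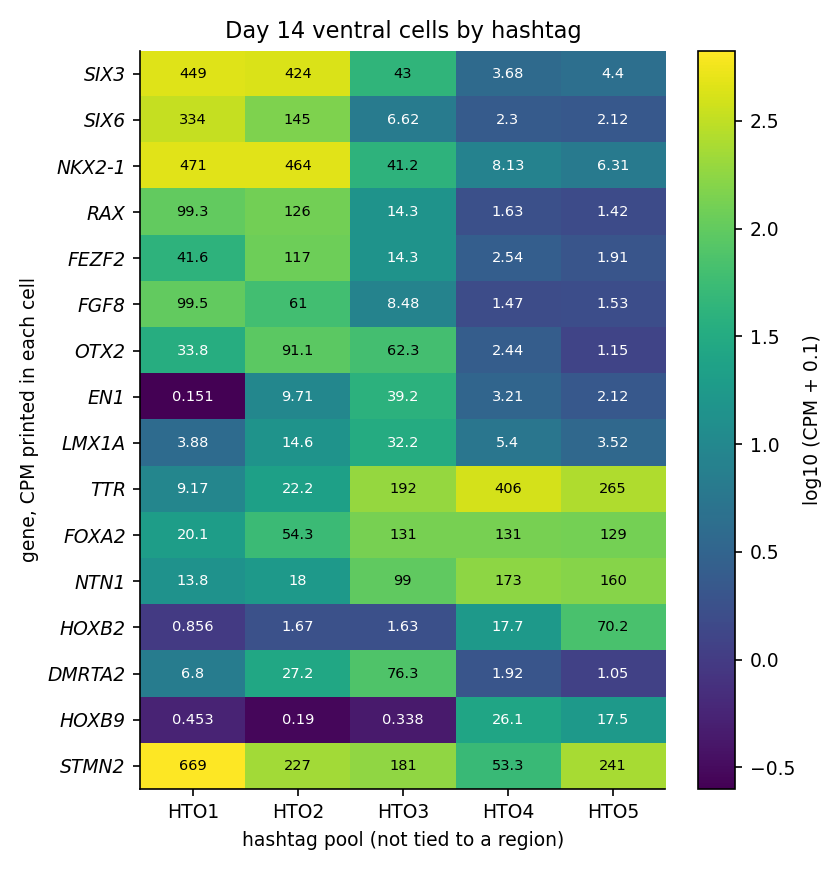
CPM of 16 genes in the cells of each hashtag pool of the day 14 ventral library, coloured by log10 of CPM + 0.1. NKX2-1 ran from 471 CPM in HTO1 to 6.31 in HTO5 and HOXB2 from 0.856 to 70.2.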

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

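In the hashtag library 4.86% of the counts matched no hashtag. The file labels them unmapped, no comparison uses them, and their origin was not tested.

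The difference between ventral and dorsal tissue changed sign from day 1 to day 2 for 3 genes that resemble the mitochondrial 16S RNA. The log2 ratio went from -1.51 to 1.26 for MTRNR2L10, from -1.68 to 1.17 for MTRNR2L12 and from -1.39 to 1.10 for MTRNR2L8. These genes are near-identical copies of one another and of mitochondrial sequence, so reads may be shared among them. At day 1 they were higher in the dorsal library, although most of its kept cells had few mitochondrial UMIs. At day 14 MTRNR2L10 and MTRNR2L8 were far lower in ventral than in dorsal tissue, and MTRNR2L12 was not. The cause was not tested.

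At day 14, 42 genes measured at 10 CPM or more in each of the 8 other cDNA libraries were at least 3-fold higher in the ventral library than in any of them, among them IGFBP2 (1856 against 43.6 to 532 CPM), GNAS, MEST, KCNQ1OT1, NES (585 against 60.9 to 170 CPM), JUND, QKI and METRN. A library-wide trend with GC content at the 3' end accounts for little of this. Their median log2 ratio to the highest other library was 1.81 after a GC correction and 1.82 before. The genes were picked at 3-fold or more, so a value below the limit of 1 for this test could hardly have come out. Their median GC content of 39.1% lay within the middle 95% of matched random lists (36.7% to 46.3%). Of the set 14.3% had an overlapping gene or a named pseudogene, against a median of 28.6% in random lists, so such genes were not over-represented. This cannot exclude shared reads. The minimum of 10 CPM in every other library leaves out genes whose reads are lost there. Ventral identity of the cells stays open. The median log2 ratio to the dorsal rounds was 1.61 in the ventral cluster with the lowest ventral neural tube list, past the limit of 1 set beforehand, but that limit was wrong for this cluster. It held 26 mesenchyme-like cells and still had 182 CPM of that list, against 17.7 to 41.2 CPM in the dorsal rounds, so no cluster lacked ventral expression. Over all clusters the ratio was 1.56 to 2.68. Also open are a difference in library chemistry or read processing, which only a ventral and a dorsal library made together would separate from biology, and an effect of the SHH activators on every cell of the tissue. The other way, 15 genes were at least 3-fold lower in the ventral library than in any other, among them RPL27A, MTRNR2L8 (14.2 against a dorsal mean of 308 CPM), NACA2 (1.06 against 76.2 CPM) and MTRNR2L10 (0.0861 against 125 CPM). The SHH repressed gene GLI2 (3.31 against 12.4 to 20.7 CPM in the other libraries) and the BMP target ID2 (25.3 against 94.6 to 311 CPM) were in this set too. What lowered these was not tested.

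At day 2, 27 genes were at 10 CPM or more in the dorsal library and at least 3-fold higher there than in any other, among them RPL17, NDUFA13, FOXP1, SLITRK4, CXCL14, GABARAP and EEF1G. Of the 26 with an annotation 53.8% had an overlapping gene or a named pseudogene, against a median of 26.9% and a middle 95% of 11.5% to 46.2% in matched random lists, a test chosen after the list had been seen. This is consistent with reads shared between genes as the cause for part of the set. A library-wide trend with GC content accounts for little of it, since the median log2 ratio was 1.98 after the GC correction and 1.91 before. These genes too were picked at 3-fold or more, so that ratio could hardly have come out below 1. Their median GC content of 40% lay within the middle 95% of matched random lists (35.7% to 48.1%). A biological cause could not be tested with 1 library, and genes without an overlap, such as SLITRK4 and CXCL14, remain unexplained.

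Among the day 14 dorsal rounds PAX8, FGF17, HOXB1, HOXA2 and HOXB2 differed by at least 3-fold. A difference in scaling between rounds could shift these ratios little, since the TMM factors of rounds 1 to 3 were 0.944, 0.950 and 0.978. In a test chosen after the data were seen, the median ratio of highest to lowest round was 13.3 after thinning to one total and TMM scaling. The genes had been picked for CPM at least 3-fold apart, so that test could hardly have come out otherwise and adds no support. A general difference between the libraries was not seen in the 20 cell cycle genes. Their median ratio of highest to lowest round was 1.08, below the limit set beforehand. This list alone cannot exclude a difference that affects other genes, since the ratio was 2.43 for neural crest genes and 2.41 for BMP targets. Different shares of cells from different regions would leave the hindbrain genes in fewer cells than an even spread. The observed share in round 3, with cells thinned to 3000 UMIs, was 0.721 of the even share (32.8% against 45.4% of cells), between the limits of 0.7 and 0.9 set beforehand, so this test cannot tell. It also covered the hindbrain genes only, not FGF17 or PAX8. In rounds 1 to 3 the cluster led by HOXB1 and HOXB2 held 0.946%, 6.59% and 21.8% of cells. The cluster led by FGF17 and PAX8 held 19.2%, 0.659% and 0.0717%. These shares differed in the direction of the genes. They were made from the same counts and depend on which rounds are clustered together, so they are no separate test.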

How the results depend on the processing

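Under every alternative the list medians of pluripotency and WNT targets against day 0 kept their direction, as did SHH pathway targets in ventral against dorsal tissue at days 1 and 2. The pluripotency median in ventral against dorsal tissue, near 0 at day 1, did not. In dorsal tissue at day 1 the pluripotency median of -0.60 was -0.54 with TMM and -0.66 with the mean of each cell's CPM, and early neuroectoderm was -0.13 with the latter against 0.04, a value near 0 in each. In ventral tissue at day 1 pluripotency was -0.69 with TMM, -0.76 with 5 CPM added and -0.86 with no minimum against -0.80, early neuroectoderm was 0.15 with TMM against -0.00, and WNT targets 2.03 with TMM against 1.89. In dorsal tissue at day 2 pluripotency was -1.70 with TMM and -1.73 with 5 CPM added against -1.85, and early neuroectoderm 1.12 with TMM, 0.95 without barcodes of few mitochondrial UMIs and 0.16 with no minimum against 0.77. In ventral tissue at day 2 pluripotency was -1.62 and -1.80 against -1.85, and early neuroectoderm 1.13 with TMM, 0.83 with 5 CPM added and 0.0665 with no minimum against 0.88. WNT targets in these 4 comparisons, in the order day 1 dorsal, day 1 ventral, day 2 dorsal and day 2 ventral, were 1.19, 1.17, 1.21 and 0.93 with 5 CPM added, and 0.50, 0.98, 0.79 and 0.63 with no minimum. A larger added value and genes near 0 CPM both pull a ratio of low counts towards 0 by construction. For ventral against dorsal tissue the SHH median at day 1 of 1.01 was 1.46 with the mean of each cell's CPM, 0.29 without barcodes of few mitochondrial UMIs, 0.75 with 5 CPM added and 0.19 with no minimum, and at day 2 it was 0.69 with 5 CPM added against 0.92. At day 1 this list held 1 gene, PTCH1, but 2 without those barcodes and 4 with no minimum, so 0.29 and 0.19 are medians over more genes. Why the mean of each cell's CPM gave a higher value was not tested.

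At day 14 the median of the ventral neural tube list was 5.18 to 5.53 without a round in turn (5.45 without round 1, 5.53 without round 2) against 5.15. That of the dorsal neural tube list was -1.38 to -0.21 against -1.04, nearest 0 without round 1. In plain CPM, without TMM scaling, the dorsal neural tube median against single rounds ran from -1.48 to 0.21. In day 14 against day 2 the BMP target median of 1.09 reversed to -0.0480 without round 1, the round with the most ID3. Leaving out a round gave 3804 to 5828 genes up and 2963 to 5095 down in ventral against dorsal tissue, and 3105 to 4987 up and 3010 to 4642 down in day 14 against day 2, with fewer degrees of freedom. DESeq2 made 91.5% and 81.3% of the same calls. In ventral against dorsal tissue the excess of genes up over genes down turned with DESeq2, which called 4394 up and 4647 down against 5028 and 4281 in edgeR. Of the named genes AXIN2 and GLI1 in day 14 against day 2, and ATF3, KRT8, LDHA, POU5F1, SMAD9 and ZNRF3 in ventral against dorsal tissue, lost their call under at least 1 alternative. The median coefficient of variation among rounds was 3.27% to 5.40% without a round in turn, lowest without round 1. Hashtag singlets were 83.9% by the ratio rule and 79.8% with every barcode against 85.3%. The neuron-like share of ventral cells was 5.14% at Leiden resolution 1, 9.73% with doublets kept and 8.95% with the strict filter against 7.0%. In the dorsal rounds the hindbrain progenitor-like share of round 1 was 0.946% with all rounds and 8.02% without round 3, and the forebrain progenitor-like share of round 3 was 22.2% with all rounds and 35.5% without round 2. Without round 1 neither a floor plate-like nor a roof plate-like class was found. The cause of these last changes was not tested. Depth limits the dorsal libraries of days 1 and 2 most, where 1 count is 0.0485 and 0.0490 CPM.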

Other observations

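Lists that belong to no main question give further differences from day 0 in the first days. Of 13 proneural factors 2 were measured, with medians of -0.88, -0.58, -0.70 and -0.58, at percentiles 4.48, 11.2, 21.5 and 23.5 of random lists, at day 1 dorsal, day 1 ventral, day 2 dorsal and day 2 ventral. The neuronal list was at 0.27, 0.28, 0.41 and 0.37 and the cell cycle list at 0.37, 0.36, 0.10 and 0.22. The 3 measured neural crest genes had medians of -1.12, -0.90, -2.11 and -2.04, with 2, 1, 2 and 2 of them at least 2-fold lower, and the vascular receptor KDR, the only measured gene of the endothelium and blood list, was 14.0-, 10.6-, 7.79- and 6.31-fold lower. Mesenchyme genes had medians of 0.58, 0.27, -0.28 and -0.96, with TAGLN higher at day 1 and lower at day 2. The SHH repressed receptors BOC, GLI2 and GLI3 had medians of 0.17, 0.14, 0.68 and 0.35. The midbrain and isthmus list was at -1.12, -1.50, 1.37 and 2.53 over 1, 1, 2 and 3 measured genes, with SPRY1 lower throughout and PAX2 higher at day 2, and the hindbrain list at 2.39, 2.28, 2.10 and 1.76 rested on GBX2 and PHOX2A, and on GBX2 alone at day 2 ventral. The choroid plexus and roof plate list held OTX2 alone, and no spinal cord gene reached 5 CPM. The stress list was at -0.01, 0.09, 0.07 and 0.71, with FOSB and FOS higher at day 2.

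At day 14 ventral tissue also differed from dorsal tissue in genes of other lists. In the edgeR fit the mesenchymal genes TWIST1, PRRX2 and COL3A1 rose to 8.05, 15.7 and 7.74 CPM. The 8 measured genes of that list had a median log2 fold change of 2.29, against 0.38 for matched random lists. VEGFA rose from 5.86 to 43.5 CPM while the glucose transporter SLC2A1 fell from 210 to 62.4 CPM. The 8 midbrain and isthmus genes went both ways, with a median log2 fold change of -0.82 and BARHL1 lower. The 8 hindbrain genes did too, with a median of -0.54 and PHOX2A at 7.47 against 0.135 CPM. In plain CPM the hindbrain median ran from -0.36 to 2.72 against single rounds. SMAD7 of the NODAL list rose, as did APCDD1 and ZNRF3 of the WNT list (ZNRF3 lost its call with the GC trend removed) and ID4 of the BMP list, while ID2 fell from 158 to 25.3 CPM. ID2 was also among the genes at least 3-fold lower in the ventral library than in any other, whose cause was not tested. HOXB8 and HOXB9, the measured spinal cord genes, did not pass.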
